A study of Saccharomyces cerevisiae with 210 samples.

How the data were processed

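RNA levels were measured in Saccharomyces cerevisiae of the diploid background BY4743, per the labels, in wild type and in 6 mutants named glr1, gpx1, gpx2, grx1, grx2 and yap1. Each genotype was grown as 6 batch cultures, 3 exposed to 0.19 mM CHP and 3 left as controls. The labels use the abbreviation CHP only; it is read here as cumene hydroperoxide. Every culture was sampled at 0, 3, 6, 12 and 20 min, with the 0 min sample taken before the oxidant was added, per the labels. This gives 210 arrays in 70 groups of 3 cultures. The replicate is the culture, and the 5 samples of a culture are repeated samples of it.

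Per the labels' protocols, RNA was extracted with hot phenol, labelled with biotin and hybridized to Affymetrix Yeast Genome S98 arrays. The deposited table holds log2 expression values made by the authors with RMA, the only processing tool that the labels name. Its version, its settings and whether all arrays were processed together are not given in the sources used here. The values run from 1.59 to 14.57. The median of the array medians was 6.23 in wild type and glr1 and 6.24 in yap1. It was 6.19 in gpx1, 6.14 in gpx2, 6.17 in grx1 and 6.18 in grx2. Raw array files were not analysed here.

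The table holds 9335 probe sets, of which 60 are controls. The gene table that came with the array names 1 gene for 6504 probe sets, several genes for 328 and none for 2443. One probe set was kept per gene, the one with the highest mean over all arrays where several named the gene (315 genes). This left 5656 genes. Locus tags and neighbouring genes were taken from the RefSeq annotation of assembly R64. No genome build is named for the array, so no coordinates are given.

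Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with 70 group means, 140 residual degrees of freedom and default empirical Bayes settings. P-values were adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. The response at a time is CHP minus control at that time (3 cultures against 3). The difference of a mutant's response is its response minus that of wild type at 20 min (12 cultures). The comparison before CHP sets the 6 cultures of a mutant against the 6 of wild type at 0 min. All mutants are compared with the same 6 wild-type cultures, so an unusual wild-type culture enters every one of these comparisons. The 5 samples of a culture were treated as independent in this fit. The correlation within a culture was 0.264, and a fit with the culture as a random block was run as an alternative.

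Gene groups were fixed as lists from general knowledge of yeast genes before the data were examined. They cover the Yap1 regulon, the thioredoxin and peroxiredoxin system, the glutathione and glutaredoxin system, superoxide dismutases and catalases, multidrug transport, and stress transcription factors. They also cover Msn2/4 general stress genes, Hsf1 chaperones, the proteasome, cytosolic ribosomal proteins, ribosome biogenesis, sulfur assimilation with methionine synthesis, pentose phosphate with NADPH supply, and iron uptake (Aft1 targets). The rest are ergosterol synthesis, amino acid synthesis (Gcn4 targets), glycolysis, the TCA cycle with the respiratory chain, peroxisome with fatty acid beta-oxidation, the unfolded protein response, and autophagy with vacuolar proteases. Cell-cycle lists hold G1/S cyclins with DNA replication, G2/M genes, and daughter with M/G1 genes. Lists for other cell types hold haploid and mating genes, and sporulation and meiosis genes. The core histone list had 2 of 8 members on the array and was not tested, since a list needs 5. Each list was tested with camera in limma, with a preset correlation of 0.01 and adjustment over the 26 lists, and again with the correlation estimated from the data. Members past the threshold are counted with p-values adjusted over all genes and also over the list alone. In wild type all lists are described. In the mutants the lists described are the Yap1 regulon and those past the threshold with at least 5 members past it in the same direction, a choice made after the data were seen.

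Genes are named by rules set beforehand, the largest changes of a comparison or of a list among those past the threshold. The pipeline was tested on simulated data. In a simulated wild-type response at 20 min, it recovered 41% of genes changed by 0.5 and 98% of those changed by 1 on the log2 scale, with 7 false calls of 146. For the yap1 difference of response these shares were 12% and 76%, with 1 false call of 89. It made 0 calls in simulated comparisons without a change. A list shifted by 0.3 was called at an adjusted p of 5.3e-18 with 0 other lists called. The simulated noise was independent between genes and between arrays, without the correlations within a culture and between genes of the real data. These figures therefore do not measure false calls that come from shared effects of a culture or batch.

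The alternatives were quantile normalization of the deposited values, centring of each array on its median, all probe sets, and removal of the third of genes with the lowest mean. Others were a 2-fold minimum, the genotypes compared alone, the replicate number as a block, each culture left out in turn, and the change from each culture's own 0 min array. Times other than 20 min, the mean of the other genotypes as reference, and the control arm over all times were also used. After the data were seen, 3 more were added that leave out 1 array each: grx2, CHP replicate 2 at 20 min, wild type, CHP replicate 1 at 0 min, and yap1, control replicate 1 at 0 min. Genes past the threshold were also counted for other splits of the cultures into groups of the same size. Figures were drawn with matplotlib 3.10.9. All 210 arrays are in the main comparisons.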

Results

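Each mutant had a low signal for its own deleted gene in all of its arrays. GLR1 averaged 4.11 on the log2 scale over the 30 arrays of glr1 and 9.39 in wild type, GRX1 4.61 in grx1 against 10.28, and GRX2 4.59 in grx2 against 10.01. GPX2 averaged 3.67 in gpx2 against 7.30, and YAP1 3.50 in yap1 against 6.66. GPX1 was dim in wild type (5.39, above 20% of the genes on the array), so its value of 4.13 in gpx1 is a weaker check. GPX2 was also low in yap1 (4.74).

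In wild type, CHP raised a small set of oxidant-defence genes within 3 min, led by the sulfiredoxin gene SRX1, and lowered G1 cyclins. By 6 min most of the Yap1 regulon had risen and genes of all cell-cycle phases had fallen. By 12 and 20 min ribosome biogenesis genes fell in large numbers and general stress genes rose, the latter a call lost with the estimated correlation (adjusted p 0.0629 and 0.0619). Between the 2 arms limma called 0 genes at 0 min, with 242 at an unadjusted p below 0.05. In the 0 min array of CHP replicate 1, however, SRX1 stood at 10.99, against 6.13 and 6.34 in the other 2 cultures of that arm.

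At 3 min 38 genes were higher and 6 lower in CHP cultures (18 and 1 of them by at least 2-fold). SRX1 rose by 5.21 (SE 0.32), YHK8 by 2.91, GRE2 by 2.03, GPX2 by 1.83 and FRM2 by 1.77. PCL1 (-1.06), YOX1 (-0.88), CLN1 (-0.63), TIP20 (-0.60) and CLN2 (-0.52) fell. In the Yap1 regulon 14 of 30 genes rose (21 adjusted over the list alone), with an adjusted p of 1.19e-59. TRR1, TSA2 and TRX2 rose by 0.71, 0.65 and 0.58, and the stress transcription factors ROX1, CIN5, RPN4 and AFT2 by 1.53, 0.90, 0.78 and 0.66. The list of those factors had a median of -0.01 and a mean of 0.10, and its call was lost with the estimated correlation (adjusted p 0.302). The glutathione and glutaredoxin list likewise had a median of -0.06 and a mean of 0.13 (adjusted p 0.268 with the estimated correlation). Of the G1/S list 4 genes fell, CLB6 (-0.74) among them. The count of 44 genes at 3 min ran from 19 without CHP replicate 2 to 81 without CHP replicate 1, and was 27 without control replicate 2 and 25 without CHP replicate 3. Among the falls, TIP20 and CLN2 each lost the call without any one of 5 of the 6 cultures (values of -0.50 to -0.62 and -0.48 to -0.53), CLN1 without CHP replicate 2 (-0.55) or 3 (-0.58), and PCL1 without CHP replicate 2 (-0.96).

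At 6 min 229 genes were higher and 491 lower (99 and 15 by at least 2-fold). YHK8 rose by 6.78, SRX1 by 6.28, FRM2 by 4.82, HSP30 by 3.90 and OYE3 by 3.70, while YOX1 (-2.29), PCL1 (-1.74), CLN1 (-1.53), SFG1 (-1.52) and HLR1 (-1.43) fell. Of the Yap1 regulon 24 genes had risen, and CTA1, CCP1 and SOD2 had risen by 3.49, 2.12 and 1.48. In the G2/M list 11 of 15 genes fell (CLB1 -0.93, CLB2 -0.88; 13 adjusted over the list alone), and in the daughter and M/G1 list 8 of 14 (CDC6 -1.03). At 12 min the counts were 604 and 1104, and ribosome biogenesis genes had joined the falls (69 of 77, NSR1 -2.49). In sulfur assimilation and methionine synthesis 12 of 26 genes rose at 12 min (STR3 3.35, MET1 1.88; 14 adjusted over the list alone), a call lost with the estimated correlation (adjusted p 0.253). Of the 229 and 491 genes of 6 min, 153 and 252 were also past the threshold in the same direction at 20 min. The higher share at 6 min depends on scale, 31.8% as deposited, 46.2% after quantile normalization and 60.8% with arrays centred on their medians. The count of 720 at 6 min fell to 386 without control replicate 1, 475 without CHP replicate 2 and 358 without CHP replicate 3.

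**Figure D1:**
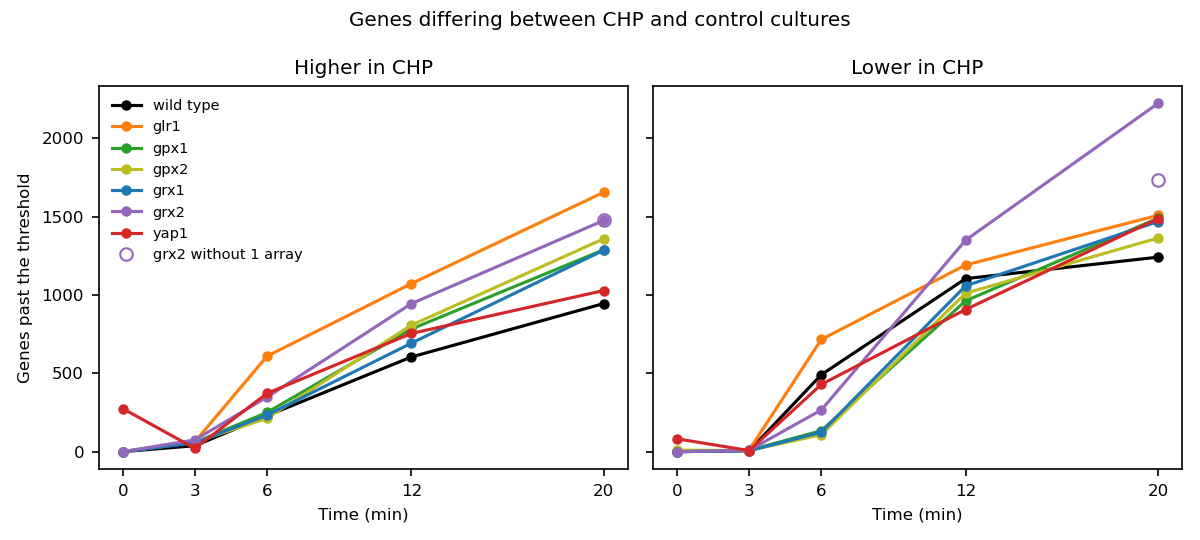
Genes past the threshold (y axis) that were higher (left) or lower (right) in 3 CHP cultures than in 3 control cultures at each time in minutes (x axis), one line per genotype, with an open circle for grx2 at 20 min without its array of CHP replicate 2. The 2 arms of yap1 differ at 0 min (275 higher, 82 lower), wild type goes from 0 genes at 0 min to 945 higher and 1241 lower at 20 min, and grx2 reaches 2222 lower, 1732 without that array.

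At 20 min 945 genes were higher and 1241 lower in wild type (271 and 341 by at least 2-fold). Among genes whose CHP and control arrays did not overlap, the largest rises were YHK8 (6.93, SE 0.26), FRM2 (5.92), OYE3 (5.86), SRX1 (5.69), TSA2 (5.61), MNC1 (4.82), OSI1 (4.80), YPR145C-A (4.43), GTT2 (4.07), GPX2 (3.90), DIA1 (3.78) and DDR2 (3.74). The largest falls among such genes were HPT1 (-3.77), NSR1 (-3.73), INA1 (-3.40), BIO3 (-3.28), BIO5 (-3.16), LYS4 (-3.02), RNR1 (-2.90), TOS6 (-2.62), SFG1 (-2.57), MYG1 (-2.55), YOX1 (-2.49) and FKH1 (-2.43). BIO3 and BIO5 already stood higher in the control arm at 0 min (BIO3 9.07 against 7.90, BIO5 9.27 against 7.74), so part of their fall was there before CHP. The higher share was 43.2% as deposited and 56.4% with arrays centred on their medians, and at 12 min 35.4% and 56%.

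The redox groups rose together at 20 min. In the Yap1 regulon 27 of 30 genes rose and 0 fell, with a median of 1.91 and an adjusted p of 6.07e-40. In the thioredoxin and peroxiredoxin system 9 of 13 rose (TSA2, PRX1 by 2.40, TRR1 by 1.76), and in the glutathione and glutaredoxin system 15 of 24 rose and 1 fell (ECM4 3.25, YCF1 1.76; 16 adjusted over the list alone). Superoxide dismutases and catalases rose in 5 of 6 cases, CTA1 by 2.98, SOD2 by 2.41 and CCS1 by 2.07 (6 adjusted over the list alone). Multidrug transporters rose in 7 of 20 cases, ATR1 by 2.17 and FLR1 by 2.02. These 5 lists kept their calls with the estimated correlation. Pentose phosphate and NADPH genes rose in 5 of 18 cases and fell in 2, SOL4 by 1.47 up and RKI1 by -1.67 (adjusted p 0.082).

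Stress and protein quality genes rose less evenly at 20 min. Of the Msn2/4 general stress genes 27 of 36 rose and 0 fell, with MSC1 at 2.35, HSP42 at 2.08 and RTC3 at 2.00 (30 adjusted over the list alone; adjusted p 0.0619 with the estimated correlation). Autophagy and vacuolar protease genes rose in 11 of 21 cases, ATG5 by 2.67, APE1 by 2.04 and PRB1 by 1.72, and kept their call (adjusted p 0.0237). Proteasome genes rose in 20 of 32 cases by small amounts, RPN9 and PRE8 by 0.75, RPN12 by 0.73 (adjusted p 0.252 with the estimated correlation). Of 30 stress transcription factors 10 rose and 2 fell, YRR1 by 1.46 and CIN5 by 1.22 up (11 and 3 adjusted over the list alone; adjusted p 0.248). Hsf1 chaperones split, 6 of 26 up (HSP104 1.10, HSP82 0.92) and YDJ1 down (-0.88), 5 and 1 adjusted over the list alone, with an adjusted p of 0.553. Peroxisome and beta-oxidation genes rose in 9 of 19 cases and fell in 2 (SPS19 0.81, PEX11 -0.84; adjusted p 0.105), and iron uptake genes rose in 8 of 25 and fell in 1 (HMX1 2.27, FRE1 1.80; adjusted p 0.606), all with the estimated correlation.

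Growth and cell-cycle groups fell at 20 min. In ribosome biogenesis 73 of 77 genes fell and 0 rose, with a median of -1.39 and adjusted p-values of 5.18e-30 and, with the estimated correlation, 0.0253 (RRP12 -2.18, DBP3 -2.08). Of the G1/S list 18 of 23 genes fell (CLB6 -2.12, CLN2 -1.90, POL1 -1.74; 21 adjusted over the list alone) and of the G2/M list 13 of 15 (ALK1 -1.96, CLB1 -1.68, CDC5 -1.67; 14 adjusted over the list alone). Ergosterol synthesis fell in 12 of 26 cases, CYB5 by -2.27 and ERG3 by -2.20 (adjusted p 0.0451 with the estimated correlation). Cytosolic ribosomal protein genes fell in 34 of 81 cases and 1 rose, RPL7B by -1.66 and RPP1 by -1.39 (adjusted p 0.368), and TCA cycle and respiratory chain genes fell in 27 of 43, ACO1 by -2.29 and COX4 by -1.58 (29 adjusted over the list alone; adjusted p 0.252). Daughter and M/G1 genes fell in 10 of 14 cases (DSE4 -1.12; 11 adjusted over the list alone; adjusted p 0.0577).

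Several groups had no call at 20 min with the preset correlation. Amino acid synthesis genes went both ways, 9 of 43 up and 15 down, ARG3 and SER2 each by -1.64 (adjusted p 0.256; 10 up over the list alone). Sulfur assimilation no longer differed (2 of 26 up, 2 down; STR2 1.02, SUL2 -0.89; 1 down over the list alone; adjusted p 0.8). Glycolysis (1 of 16 up, TDH1 1.36, and 3 down; adjusted p 0.691) and the unfolded protein response (1 of 17 up, HAC1 0.70, and 5 down, EUG1 -0.94; adjusted p 0.664) stayed near 0. Haploid and mating genes (3 of 22 down, AGA1 -0.66; 1 over the list alone; adjusted p 0.691) and sporulation genes (1 of 22 up, 4 down, SPS4 -0.69; 0 up over the list alone; adjusted p 0.8) did so too.

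**Figure D2:**
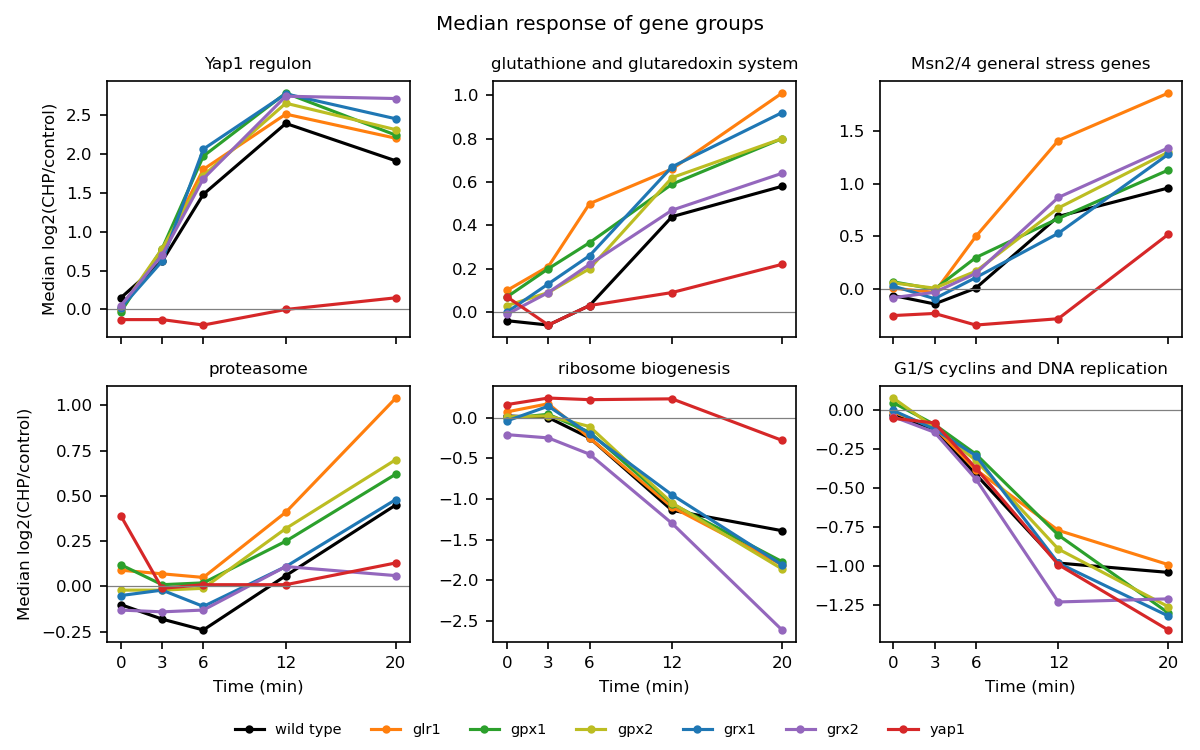
Median log2 difference of CHP and control cultures (y axis) over the members of 6 gene groups at each time in minutes (x axis), one line per genotype, with the array of grx2, CHP replicate 2 at 20 min included. The Yap1 regulon has a median of 1.91 in wild type at 20 min and stays near 0 in yap1, while ribosome biogenesis falls in wild type to -1.39.

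All mutants responded to CHP at 20 min, with 1655 genes higher and 1508 lower in glr1, 1288 and 1489 in gpx1, 1358 and 1363 in gpx2, 1285 and 1468 in grx1, 1475 and 2222 in grx2, and 1028 and 1487 in yap1. Without the array of CHP replicate 2, whose values stand apart from all others, grx2 had 1481 and 1732. With arrays centred on their medians the higher share was 52.3% in place of 39.9% for grx2 and 51.2% in place of 40.9% for yap1. It was 53.6% in place of 46.4% for gpx1, 54.8% in place of 49.9% for gpx2 and 54.2% in place of 46.7% for grx1. Of the 271 genes that rose at least 2-fold in wild type, 204 rose in yap1, and at least 267 in every other mutant. YHK8 rose in all 6 mutants, by 6.12 in yap1 and by 6.70 to 7.10 in the others.

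In yap1 most of the Yap1 regulon responded less to CHP than in wild type, and genes outside it differed too. Of the genes that led the wild-type rise, SRX1, FRM2 and OYE3 did not rise in yap1, TSA2 rose by 1.14, and YHK8 still rose by 6.12. Ribosome biogenesis genes fell less, a call lost with the estimated correlation (adjusted p 0.139), and HSP30, GPD2 and FRE4 rose far more. At 20 min the response was higher on the log2 scale at 653 genes and lower at 659 (294 and 186 by at least 2-fold), 1312 in all, and the mutant already differed at 20, 469 and 1270 genes at 3, 6 and 12 min. The largest losses were OYE3 (-6.43, SE 0.32), FRM2 (-6.07), SRX1 (-5.82), OSI1 (-5.23), TSA2 (-4.47), AAD4 (-4.19), GTT2 (-3.96), DDR2 (-3.70), GPX2 (-3.53) and YML131W (-3.39). SRX1 changed by -0.13 in yap1 itself at 20 min, CTA1 by -0.07 and TRX2 by 0.21. The largest gains were HSP30 (5.60, SE 0.46), GPD2 (4.53), FRE4 (4.48), BIO3 (3.98, SE 1.02), YNL194C (3.62) and BIO5 (3.32, SE 1.09), and for BIO3 and BIO5 the difference lies in the fall in wild type. HSP30 changed its sign over time: it was lower than in wild type by -4.47 at 6 min and -1.38 at 12 min. It rose early in wild type (3.90 at 6 min, 1.89 at 20 min) and late in yap1 (-0.58 and 7.49).

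Of the Yap1 regulon 24 of 30 genes responded less in yap1 and 0 more, with a median of -1.58 and an adjusted p of 3.05e-38, kept with the estimated correlation (2.94e-08). The thioredoxin and peroxiredoxin system (6 of 13 lower, PRX1 -3.05, TRR1 -1.56) and superoxide dismutases and catalases (5 of 6 lower, CTA1 -3.05, SOD2 -2.49) kept their calls too, while CTT1 of the latter was higher by 2.56. In the glutathione and glutaredoxin system 10 of 24 were lower and 1 higher, ECM4 by -2.88 (adjusted p 0.15 with the estimated correlation). Msn2/4 genes went both ways, 13 of 36 lower (GSY1 -3.17, GPH1 -2.68; 15 adjusted over the list alone) and 6 higher (adjusted p 0.568). Proteasome genes were lower in 8 of 32 cases, RPT2 by -0.89 (adjusted p 0.509), and G2/M genes lower in 5 of 15 and higher in 1, CHS2 by -1.04 and CLB1 by 1.67 (7 lower over the list alone; adjusted p 0.476).

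Growth genes responded higher in yap1 than in wild type, in calls that were all lost with the estimated correlation, whose adjusted p closes each bracket here. Ribosome biogenesis was higher in 55 of 77 cases (NSR1 2.94, NOP15 1.99; 59 adjusted over the list alone; 0.139). Amino acid synthesis, which had no call in wild type, was higher in 22 of 43 with 1 lower (CPA1 2.48, ARG3 2.21; 24 over the list alone; 0.159), and cytosolic ribosomal proteins in 16 of 81 with 1 lower (RPL22B 1.62; 0.476). TCA cycle and respiratory chain genes were higher in 11 of 43 cases and lower in 3 (QCR7 1.48, CYC1 -1.60; 13 higher over the list alone; 0.568), and daughter and M/G1 genes higher in 9 of 14 (SCW11 1.05; 10 higher and 1 lower over the list alone; 0.15). Of the 341 genes that fell at least 2-fold in wild type, 188 fell less in yap1, and of the 271 that rose, 92 rose less and 44 more. The 12 cultures behind this comparison moved its count between 1131 and 1309 when left out one at a time.

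**Figure D3:**
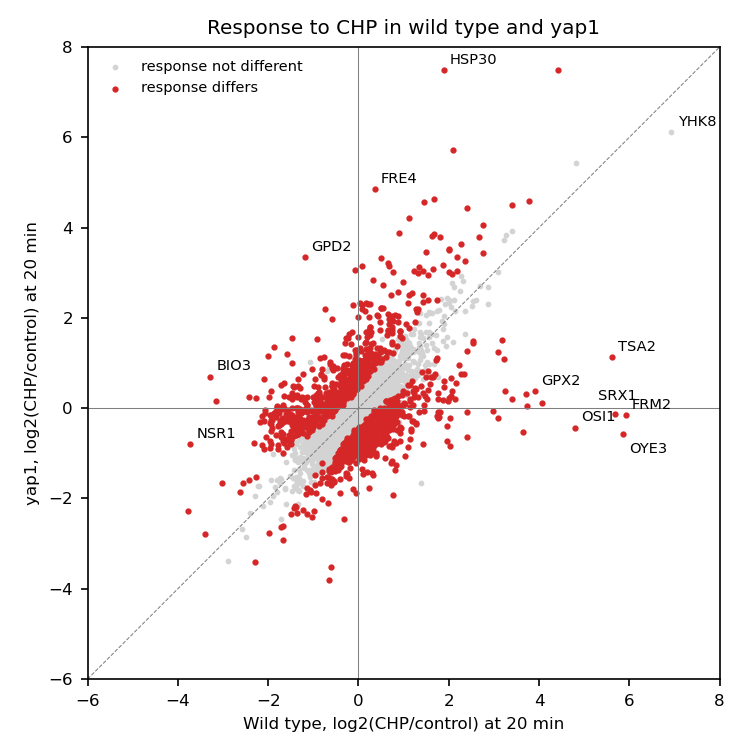
Log2 difference of CHP and control cultures at 20 min in wild type (x axis) and in yap1 (y axis), one point per gene, red where the responses differ past the threshold, with equal responses on the dashed line. SRX1, OYE3 and FRM2 rise by over 5 in wild type and stay near 0 in yap1, while HSP30 rises by 1.89 in wild type and 7.49 in yap1.

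In glr1 heat-shock genes responded more strongly to CHP than in wild type. HSP26 had 3.81 in glr1 and 0.48 in wild type, and SSA4 3.52 and 0.31. The response was higher on the log2 scale at 172 genes and lower at 115. The most raised were HSP26 (3.32, SE 0.26), SSA4 (3.20) and RTC3 (2.28), the most lowered ADH5 (-2.42), ARO5 (-2.28) and ALD5 (-2.20). Without glr1 control replicate 3 ARO5 had -0.88 and no call (adjusted p 0.172), and with only the genotypes compared its adjusted p was 0.142. Of the Hsf1 chaperones 16 of 26 responded more (HSP82 1.71, YDJ1 1.50; 22 adjusted over the list alone), with a median of 1.03 and a call kept with the estimated correlation (adjusted p 0.00462). Calls of 6 other lists were lost with the estimated correlation, whose adjusted p closes each bracket here. Msn2/4 genes were higher in 13 of 36 cases (ALD3 2.05, HSP12 1.97; 21 over the list alone; 0.0898), proteasome genes in 7 of 32 (RPT1 0.69; 25 over the list alone; 0.186) and sulfur assimilation genes in 5 of 26 (MET2 1.37, MUP1 1.34; 10 higher and 1 lower over the list alone; 0.253). Amino acid synthesis was lower in 8 of 43 cases and higher in 1 (HIS7 -1.42, CPA1 -1.35; 13 lower over the list alone; 0.172), ribosome biogenesis in 13 of 77 (NOP58 -1.34; 19 over the list alone; 0.253) and cytosolic ribosomal proteins in 8 of 81 (RPL7B -1.53; 10 over the list alone; 0.433). In the Yap1 regulon 2 of 30 were higher (GSH1 0.89, TSA1 0.37) and 1 lower (the deleted GLR1), with an adjusted p of 0.0678. At 3, 6 and 12 min the difference held 0 (463 at an unadjusted p below 0.05 in limma), 83 and 37 genes. The higher share was 59.9%, 38.7% after quantile normalization and 32.1% with centred arrays, and the count of 287 moved to 979 without glr1 control replicate 3, 483 without glr1 CHP replicate 1, 157 without glr1 CHP replicate 2, 132 without glr1 CHP replicate 3, 127 without wild-type control replicate 1, and 119 and 120 without wild-type CHP replicates 2 and 3.

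Genes that rose or fell at least 2-fold in wild type had larger median responses in grx2 at 20 min. The other mutants except yap1 showed the same by smaller margins. Past the threshold, 26 of 271 rises and 41 of 341 falls were larger in glr1, and 14 and 12 in grx1. In gpx1 0 and 4 were larger, and in gpx2 1 and 5, with 1 rise smaller in gpx2. All are set against the same wild-type cultures, so an unusually weak response there would give the same pattern. Ribosome biogenesis genes fell deeper in grx2 than in wild type. Like the calls of the 6 other lists named here, that of ribosome biogenesis was lost with the estimated correlation (adjusted p 0.259, and 0.268 for ergosterol synthesis). The response was higher on the log2 scale at 553 genes and lower at 1028, and at 407 and 465 without the array of CHP replicate 2, the library that the count depends on most. UTP6 (-2.31), EFG1 (-2.28) and UTP15 (-2.24) were the most lowered, HSP30 (3.13) and TMA10 (3.10) the most raised, and all 5 stayed past the threshold without that array. ATG17 (2.95) did not, with 0.50 and an adjusted p of 0.371. Ribosome biogenesis was lower in 62 of 77 cases (RPA34 -2.21, RRP9 -2.19; 65 adjusted over the list alone; 53 without the array), and Msn2/4 genes higher in 11 of 36 (CTT1 2.76, RTC3 2.70, ALD3 2.04; 12 without it). G2/M genes were lower in 10 of 15 cases (CDC5 -1.27; 11 over the list alone; 5 without the array), G1/S genes in 7 of 23 (PCL1 -1.95, RNR1 -1.56; 1 higher over the list alone; 6 lower without the array) and ergosterol synthesis in 11 of 26 with 1 higher (CYB5 -0.86; 12 lower over the list alone; 2 without the array). Haploid and mating genes were higher in 6 of 22 cases (SST2 2.67, FAR1 2.25, both with the array included), in 2 without the array, where the list had an adjusted p of 0.0656. That array dominates the spread of FAR1. Without it the limma adjusted p of FAR1 in the gpx2 difference went from 0.00511 to 7.26e-12 at an unchanged -2.92. The grx2 value of FAR1 can therefore not be read as a response. In the Yap1 regulon 8 of 30 were higher (AAD6 1.90, CIS1 1.80) and 1 lower, GRX2 itself. Of the wild-type 2-fold responders 103 rises and 199 falls were larger in grx2 (3 and 9 smaller), and 110 and 155 without the array (1 and 7 smaller). With all arrays their median rise was 1.50 in wild type, 2.22 in grx2 and 1.83 to 1.93 in glr1, gpx1, gpx2 and grx1. The median fall was -1.37, -2.21 and -1.68 to -1.73 in the same order. A larger median was thus not particular to grx2, and these medians were not tested. At 3, 6 and 12 min the difference held only 0, 8 and 15 genes (134 at 3 min at an unadjusted p below 0.05 in limma), and the higher share of 35% at 20 min was 45.5% after quantile normalization.

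In grx1, gpx1 and gpx2 the response at 20 min differed from that of wild type at few genes. The grx1 response was higher on the log2 scale at 24 genes, among them FMP48 (2.44), RTC3 (2.07) and HSP30 (2.05), and lower at 19, among them UTP6 (-1.42), PCL1 (-1.25) and RPA34 (-1.22), which fell further than in wild type. Ribosome biogenesis was lower in 6 of 77 cases (IPI3 -1.21; 15 adjusted over the list alone; adjusted p 0.0924 with the estimated correlation), and the Yap1 regulon had a median of 0.35 with 1 of 30 higher, MRX16 by 0.93 (5 over the list alone; adjusted p 0.0457). The gpx1 response was higher at YGL108C (1.45) and lower at 9 genes, with ZRT1 (-1.76), UTP6 (-1.11) and SFG1 (-1.09) first, which fell further than in wild type. No member of the Yap1 regulon passed in gpx1 (2 over the list alone; median 0.32, adjusted p 0.197 with the estimated correlation). The gpx2 response was higher at TRR1 (0.64) and lower at 15 genes, GPX2 itself (-3.88), FAR1 (-2.92) and HO (-2.45) first. The 2 arms of gpx2 already differed at 0 min at 11 genes, 1 higher and 10 lower in the CHP arm (1 and 7 by at least 2-fold), and with each culture's own 0 min array subtracted the responses differed at 8 genes. Haploid and mating genes were lower in 6 of 22 cases (MFA2 -2.05, STE2 -1.77; 2 higher and 7 lower over the list alone), with adjusted p-values of 6.17e-13 and 2.22e-05. The Yap1 regulon in gpx2 had TRR1 higher and GPX2 lower (6 higher over the list alone; adjusted p 0.23 with the estimated correlation).

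These small counts move with single cultures. In gpx1 ZRT1, UTP6, SFG1 and YGL108C each lost the call without any one of 8 of the 12 cultures, with ZRT1 at -1.23 and YGL108C at 0.64 without gpx1 CHP replicate 2. In grx1 PCL1 and RPA34 did so without any one of 9 cultures, HSP30 without grx1 CHP replicate 2 (1.61) or 3 (1.89) or wild-type CHP replicate 2 (1.75), and RTC3 without grx1 CHP replicate 3 (1.77) or wild-type CHP replicate 2 (1.81) or 3 (1.69). In gpx2 TRR1 did so without any one of 6 cultures, at 0.57 to 0.63. For gpx1, 10 genes became 0 without gpx1 control replicate 1, 2 or 3, gpx1 CHP replicate 2 or wild-type CHP replicate 2, 1 without wild-type CHP replicate 3, 5 without wild-type control replicate 1, 22 without wild-type CHP replicate 1, 40 (30 higher, 10 lower) without gpx1 CHP replicate 3 and 100 (61 higher, 39 lower) without gpx1 CHP replicate 1. With the mean of the 6 other genotypes as reference it was 66 (51 higher, 15 lower), so the direction of the gpx1 difference depends on the setting. For grx1, 43 genes became 132 without wild-type CHP replicate 1, 9 and 16 without wild-type CHP replicates 2 and 3, 24, 16 and 14 without grx1 control replicates 1, 2 and 3, and 69, 16 and 10 without grx1 CHP replicates 1, 2 and 3. For gpx2, 16 genes became 67 and 9 without wild-type CHP replicates 1 and 2, and 10 without gpx2 control replicate 2 or gpx2 CHP replicate 2. The higher share in grx1 was 55.8%, 69.2% after quantile normalization and 49% with centred arrays (25 higher, 26 lower). Without wild-type CHP replicate 1 it was 63 higher and 69 lower, so the balance in grx1 depends on the setting.

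**Figure D4:**
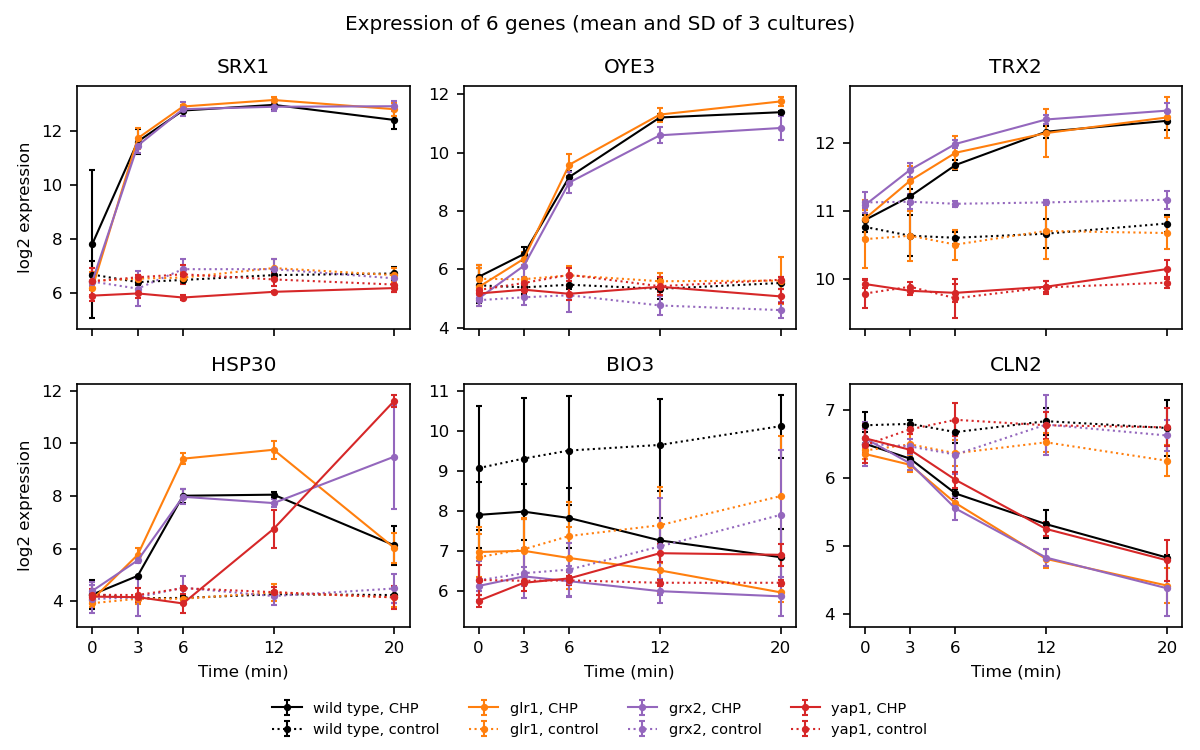
Log2 expression (y axis) of SRX1, OYE3, TRX2, HSP30, BIO3 and CLN2 at each time in minutes (x axis) in wild type, glr1, grx2 and yap1, CHP cultures as solid and control cultures as dotted lines, with points and bars for the mean and SD of 3 cultures. SRX1, OYE3 and TRX2 rise in all but yap1, HSP30 rises late in yap1, and BIO3 is higher in wild-type control cultures (9.07) than in CHP cultures (7.90) at 0 min.

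Before CHP, gpx2 stood out by cell type. Genes that diploid cells keep silent were on: MFA2 was higher by 5.25 (SE 0.13), BAR1 by 4.83, STE2 by 4.75 and FAR1 by 3.79, and 16 of 22 haploid and mating genes were higher and 1 lower, with a median of 2.03 and an adjusted p of 2.77e-80. All 6 a-specific genes passed (median 3.92), and 0 of 4 alpha-specific genes were higher (median -0.22). MFA2 lay between 12.32 and 12.59 in the 6 gpx2 arrays and between 6.89 and 7.57 in wild type. HPF1 (-3.50), BIO5 (-2.81), GPX2 (-2.62) and YDR034C-A (-2.25) were the most lowered among genes whose arrays did not overlap with wild type. BIO5 was low in grx1, grx2 and yap1 as well. Per the labels the strain is BY4743, a diploid; in every gpx2 comparison the state of these genes differs from wild type along with GPX2. In all, 357 genes were higher and 638 lower, a higher share of 35.9% (48.8% after quantile normalization, 54.1% with centred arrays).

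**Figure D5:**
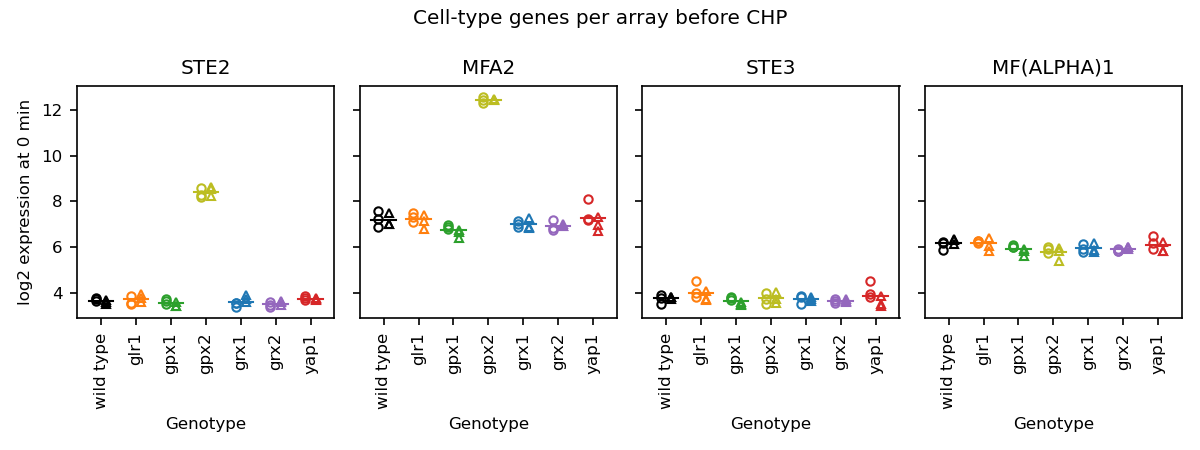
Log2 expression at 0 min (y axis) of the a-specific genes STE2 and MFA2 and the alpha-specific genes STE3 and MF(ALPHA)1 in the 7 genotypes (x axis), one point per array (circles control arm, triangles CHP arm) and a line at the mean of 6. The 6 gpx2 arrays hold MFA2 between 12.32 and 12.59, while wild type stays between 6.89 and 7.57.

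In grx2 before CHP the iron uptake genes were low, 22 of 25 lower and 0 higher, with a median of -1.13 (ARN2 -3.18, TIS11 -2.34, ENB1 -2.24, SIT1 -2.03; adjusted p 6.02e-17, 0.231 with the estimated correlation). The grx2 cultures differed among themselves, with ARN2 at 7.33 (SD 2.12) in the 3 control cultures against 10.94 (SD 0.39) in wild type. BIO5 (-2.88) and BIO3 (-2.30) were lower. BIO5 was lower by similar amounts in gpx2, grx1 and yap1 (-2.81, -2.88 and -2.85), and BIO3 in grx1 and yap1 (-2.50 and -2.48). These comparisons share the wild-type cultures, whose control arm stood higher in both genes at 0 min, so the falls cannot be assigned to single deletions. In grx2 RPL9A (1.24), SSC1 (1.06), SYO1 (1.05) and ATP20 (1.05) were higher, within 950 higher and 695 lower genes. With all probe sets (1326 higher and 1901 lower probe sets), and in the control arm over 5 times, more were lower than higher. Ribosome biogenesis was higher in 48 of 77 cases (UTP7 0.87; 52 adjusted over the list alone), Hsf1 chaperones in 13 of 26 with 1 lower (HSP82 0.82; 15 over the list alone) and glycolysis in 8 of 16 (TDH1 1.53; 9 over the list alone). Stress transcription factors were lower in 8 of 30 cases and higher in 1 (MET28 -0.57). The estimated correlation removed these calls (adjusted p-values 0.342, 0.393, 0.394 and 0.393).

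In yap1 before CHP the Yap1 regulon was already low, 11 of 30 genes, with a median of -0.29 and an adjusted p of 3.97e-21, kept with the estimated correlation (9.46e-05). GRE2 was lower by -2.14, GPX2 by -1.80 and YML131W by -1.41, and 6 of 13 thioredoxin and peroxiredoxin genes were lower and 1 higher, TRX2 by -0.96 and PRX1 by -0.83. SRX1 was lower by -1.08, and by -0.29 without the wild-type array of CHP replicate 1 (adjusted p 0.164). Among genes whose arrays did not overlap with wild type, BIO5 (-2.85), YAP1 (-2.84), BIO3 (-2.48) and YLR108C (-2.16) were the most lowered, and ANB1 (2.91), FET4 (1.77), COX5B (1.03) and HEM13 (0.90) the most raised. The falls of BIO5 and BIO3 were shared with other mutants, as given for grx2. Ribosome biogenesis was higher in 15 of 77 cases (NOP15 0.64; 18 adjusted over the list alone) and ergosterol synthesis in 8 of 26 with 1 lower (CYB5 0.64; 12 over the list alone), with adjusted p-values of 0.624 and 0.487 with the estimated correlation. In all 517 genes were higher and 174 lower, a share of 74.8%, 50.5% after quantile normalization and 41.8% with centred arrays. The 2 arms of yap1 differed at 357 genes at 0 min, and at 0 (58 at an unadjusted p below 0.05 in limma) without the array of control replicate 1.

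In glr1 before CHP only GLR1 (-5.03), PHO89 (-1.02) and 2 other genes differed, 1 higher and 3 lower in all. The glr1 count is 2 without wild-type CHP replicate 1, 7 without glr1 CHP replicate 1, 8 and 9 without glr1 control replicates 1 and 2, and 10 without wild-type control replicate 3. The gpx1 and grx1 mutants differed from wild type at many genes by small amounts, 926 higher and 715 lower in gpx1 (ADE4 1.23, TIF11 1.04, CDC3 0.99) and 689 higher and 528 lower in grx1 (ADE4 1.19, SSC1 1.06, TIF11 0.95), with RDN25-1 higher by 2.39 and 3.64. The balance turned to lower in gpx1 and grx1 with all probe sets (1393 higher and 2033 lower probe sets, 956 and 1419), in the control arm over 5 times (134 and 185, 351 and 409) and with the mean of the 6 other genotypes as reference (160 and 171, 18 and 26). Among genes whose arrays did not overlap with wild type, SRX1 (-1.24), GPX1 (-1.11), YNCK0008W (-1.07) and YNCM0018C (-1.06) were the most lowered in gpx1, and GRX1 (-5.47), BIO5 (-2.88), BIO3 (-2.50) and YJR154W (-1.85) in grx1. Without the wild-type array of CHP replicate 1 SRX1 had -0.45 in gpx1 (adjusted p 0.0133). Against the shared wild-type cultures, cytosolic ribosomal proteins were higher in gpx1, gpx2, grx1 and grx2 in 48, 26, 49 and 48 of 81 cases (RPL9A by 0.89, 0.82, 0.97 and 1.24) and TCA cycle and respiratory chain genes in 28, 19, 25 and 31 of 43 (ATP14 by 0.86 in gpx1), and the smallest adjusted p of these 8 lists with the estimated correlation was 0.342.

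Between gpx1 and grx1 themselves only 2 genes differed at 0 min. In these mutants ribosome biogenesis was higher in 25 of 77 cases in gpx1, 6 in gpx2 and 21 in grx1 (NOP56 0.60, 0.53 and 0.62), and sulfur assimilation in 10, 6 and 8 of 26 (MET14 0.68, 0.54 and 0.71). Amino acid synthesis was higher in 18 and 12 of 43 cases with 3 lower in gpx1 and grx1 (SER3 0.73 and 0.65), and glycolysis in 5 and 6 of 16 (FBA1 0.42 and 0.56). Autophagy genes were lower in 6, 6, 5 and 5 of 21 cases in gpx1, gpx2, grx1 and grx2 (ATG9 -0.44 in gpx2), Msn2/4 genes in 7 and 5 of 36 in gpx1 and grx1 (TPS2 -0.43 and -0.51), and in grx1 9 of 26 Hsf1 chaperones and 7 of 32 proteasome genes were higher with 1 lower each (HSC82 0.73, RPN5 0.55). None of these calls stood with the estimated correlation, where the adjusted p-values ran from 0.342 to 0.867. The Yap1 regulon had medians of -0.09 in glr1, -0.10 in gpx1, -0.19 in gpx2, -0.07 in grx1 and -0.07 in grx2. In that order 1, 6, 9, 5 and 8 members were lower and 0, 2, 2, 2 and 4 higher. The wild-type array of CHP replicate 1 at 0 min, with its high SRX1, enters all of these medians. Without it the glr1 median was 0.02. SRX1 then went from -0.79 to 0.00 in gpx2, from -0.99 to -0.19 in grx1 and from -0.82 to -0.03 in grx2. Its calls in these mutants were lost, and in gpx1 it kept its call at -0.45. All of these comparisons share the wild-type cultures, and without wild-type control replicate 3 the counts fell to 761 in gpx1, 542 in gpx2, 443 in grx1, 978 in grx2 and 293 in yap1. Without CHP replicate 3 of grx1 or of wild type the grx1 count was 810 or 695, and without CHP replicates 2 and 3 of wild type the yap1 count was 428 and 425.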

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

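The tests of the range of MFA2, of the alpha-specific genes, of neighbouring probe sets, of the early and late genes of a wild-type array, and of the splits in grx2 without 1 array were chosen after those patterns were seen. The other tests of this part were written down before they were run. The array of grx2 left out below was chosen after the data were seen.

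The strain behind the gpx2 cultures expressed mating genes that a diploid keeps silent, a median of 2.03 above wild type over 22 haploid and mating genes before CHP. A haploid of the BY4741 type would lack MET17, which differed by 0.11 only, and was predicted to hold more LYS2, which differed by 0.07. A contamination that varied between cultures is argued against by the range of MFA2 over the 6 arrays, 0.26. The 4 alpha-specific genes had a median difference of -0.22 beside a median of 3.92 for the 6 a-specific genes, which is consistent with a loss of the MAT alpha information in the strain, its ploidy unknown. An equal share of a-type cells in all 6 cultures, and an effect of the GPX2 deletion itself, stay open, since the series holds a single gpx2 strain. As a hypothesis, the lower response of the mating genes in gpx2 at 20 min (median -0.26) may belong to cell type and not to GPX2.

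In the array of grx2, CHP replicate 2 at 20 min, 782 probe sets lay over 2 on the log2 scale from the mean of the other 2 cultures, and its median correlation with the other arrays was 0.785, against at least 0.868 for any other. RNA of another condition or cell population is argued against by 42 genes that deviated by over 4 in 1 probe set, whose distant probe sets had a median deviation of -0.45. Deviations of probe sets with neighbouring numbers went together with a rank correlation of 0.65, against 0.172 to 0.596 in the other arrays. Deviations over 2 made up 30.8% and 34.3% of the probe sets numbered 2000 to 2500 and 2500 to 3000. They made up at most 0.2% in any range between 3500 and 6500, and 19.5% from 11000 on. Positions of the probe sets on the array were not used, so a fault in one area stays possible and is not shown by these values. Without it 872 genes, and not 1581, differed between the responses of grx2 and wild type. Apart from RNA of another cell population, no biological explanation was tested.

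In the wild-type array of CHP replicate 1 at 0 min SRX1 stood at 10.99, against 6.13 to 7.28 in the other 5 wild-type arrays of that time, and 37 genes of the early response lay 0.66 above those arrays (the other 41 arrays at 0 min lay between -0.27 and 0.38). RNA of a late CHP sample is argued against by 325 late genes, with a median of -0.05, and a swap of the 0 and 3 min samples by the early genes in the 3 min array of this culture, 0.81 above the other 0 min arrays. From 0 to 3 min the early genes changed by 0.07 in this culture, which is consistent with a 0 min sample taken after CHP was added. Its 0 and 3 min arrays correlated at 0.9976, above the other 20 CHP cultures (0.9891 to 0.9958) but not above control cultures, which reached 0.9979, so this value does not tell a separate early sample from a 3 min sample measured under both names. No biological explanation was tested.

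The responses of the mutants and of wild type differed at 20 min, by a test of the difference itself, at 287 genes in glr1, 10 in gpx1, 16 in gpx2, 43 in grx1, 1581 in grx2 and 1312 in yap1. The same test on gene groups gave medians of 1.03 for Hsf1 chaperones in glr1, -0.26 for haploid and mating genes in gpx2 and 0.35 for the Yap1 regulon in grx1. The grx1 call lay near the threshold with the estimated correlation. The median in gpx1 was close to that in grx1, as given above, and had no call with that correlation. In yap1 it gave -1.58 for the Yap1 regulon, -0.47 for the thioredoxin and peroxiredoxin system and -1.83 for superoxide dismutases and catalases.

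Of 100 splits of the 12 cultures, drawn at random with the real one among them, 4 gave as many genes as the real one in grx2 with all arrays (1581, highest other 1869). Without the array that stands apart 6 did (872, highest other 1121). As many were given by 21 splits in glr1 (real 287, highest other 1681), 11 in gpx1 (10 and 98), 11 in gpx2 (16 and 97), 8 in grx1 (43 and 98) and 11 in yap1 (1312 and 1817). Of the splits as large, 8 of 21 in glr1, 4 of 11 in gpx1, 9 of 11 in gpx2, 7 of 8 in grx1, 4 of 4 in grx2 with all arrays, 5 of 6 in grx2 without that array and 11 of 11 in yap1 kept the CHP cultures of each genotype together. Such splits keep the difference itself, so a share of 0.05 cannot decide on chance here. The highest counts with CHP cultures mixed were 1681, 98, 64, 44, 1331, 995 and 97 in that order. Mixed splits reached the real count in glr1, gpx1, gpx2, grx1 and grx2 without that array, so chance is not excluded for those counts. In grx2 with all arrays and in yap1 no mixed split did. The splits weigh counts only: single genes such as OYE3 in yap1 (-6.43, adjusted p 8.38e-41) and HSP26 in glr1 (3.32, 2.74e-22) passed their own tests by far. In glr1 and gpx1 the highest splits with CHP cultures mixed called over 5 times the real count, which points to a structure of the samples whose source was not tested.

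Values that stood apart from the other 5 arrays of their genotype at 0 min came from 8 of 105 groups tested, where chance gives about 1 in 20. In control replicate 1 of yap1 GLR1 was at 8.01 (others 8.91 to 9.15), GRX1 at 9.04 (10.04 to 10.41) and FET4 at 9.45 (8.84 to 9.03). YAP1 was at 6.91 in control replicate 1 of grx2 (6.55 to 6.62), SRX1 at 5.77 in CHP replicate 1 of gpx1 (5.98 to 6.10) and, as above, at 10.99 in wild type. BIO5 was at 6.78 in control replicate 2 of gpx2 (5.27 to 5.64), and YDR034C-A at 8.14 in CHP replicate 2 of gpx2 (6.90 to 7.30). Among 2443 probe sets that name no gene and enter only the alternative with all probe sets, 109 were higher and 100 lower in wild-type CHP cultures at 20 min, the largest rise being 2.52.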

How the results depend on the processing

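The settings without 1 array were chosen after the data were seen. Counts are genes past the threshold (probe sets where all probe sets are used), differences are those of the responses at 20 min, and the cause of the changes was not tested. The main values are 44, 720, 1708 and 2186 in wild type at 3, 6, 12 and 20 min. For glr1, gpx1, gpx2, grx1, grx2 and yap1 in that order they are 3163, 2777, 2721, 2753, 3697 and 2515 for the responses, 287, 10, 16, 43, 1581 and 1312 for the differences, and 4, 1641, 995, 1217, 1645 and 691 before CHP. For a change of 0.5 on the log2 scale the simulated recovery was 41% in a response and 12% in a difference.

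The replicate number as a block gave 73 at 3 min in wild type, differences of 571 in glr1, 30 in gpx1, 36 in gpx2 and 91 in grx1, and 57 in glr1 and 1064 in yap1 before CHP. It moved none of the other 16 counts by over 1.5 times. Numbers did not pair the cultures evenly: deviations of same-numbered cultures correlated from -0.44 to 0.70, over 0.1 in 12 of 21 cases. The own number was the best match in 8 of 21, about as many as without any pairing, since each match is among 3 cultures. In all genotypes but yap1 the correlation was at least 0.33 for number 1 and negative for number 2. A day or batch shared by number is therefore not excluded. The culture as a random block gave 17 in glr1 before CHP. With only the genotypes compared the differences were 60 in glr1, 39 in gpx1, 81 in gpx2, 193 in grx1 and 834 in grx2, and the counts before CHP 1 in glr1, 1977 in grx1 and 1091 in grx2. The mean of the 6 other genotypes as reference gave differences of 965, 66, 35, 17 and 2240 in glr1, gpx1, gpx2, grx1 and yap1, and 611, 331, 396, 44, 653 and 1496 before CHP in glr1, gpx1, gpx2, grx1, grx2 and yap1. There the Yap1 regulon in glr1 (0.02) and ribosome biogenesis in gpx2 (-0.13) turned their direction before CHP. The control arm over 5 times gave 319 in gpx1, 760 in grx1 and 103 in yap1 before CHP.

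Without the third of genes with the lowest mean the differences were 10 in gpx2, 24 in grx1 and 960 in grx2, with 2 in glr1 before CHP. Quantile normalization gave differences of 0 in gpx1 and 13 in grx1, and 15 in glr1 before CHP. Arrays centred on their medians gave a difference of 31 in gpx2 and turned stress transcription factors at 3 min (0.05), and iron uptake (0.10) and peroxisome genes (0.11) at 6 min, in wild type. All probe sets gave 3426, 1957, 2375 and 3227 probe sets in gpx1, gpx2, grx1 and grx2 before CHP. The 2-fold minimum gave 19, 114, 436 and 612 in wild type at 3, 6, 12 and 20 min, and responses of 1086, 936, 930, 952, 1500 and 602 in glr1, gpx1, gpx2, grx1, grx2 and yap1. With it the differences were 86, 6, 27, 574 and 480 in glr1, gpx1, grx1, grx2 and yap1, and the counts before CHP 2, 18, 47, 13, 38 and 19 in the order above. The change from the culture's own 0 min array gave 12 and 288 in wild type at 3 and 6 min, and differences of 116, 3, 8 and 10 in glr1, gpx1, gpx2 and grx1. Without the outlying grx2 array the differences were 25 in gpx2 and 872 in grx2, with 10 in glr1 before CHP. Without the early wild-type array glr1 had 2 before CHP, and its Yap1 regulon a median of 0.02. In that setting 4 list calls were lost. Without the yap1 array of control replicate 1 none of the 23 counts moved by over 1.5 times.

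At 6 min in place of 20 min the responses were 1325, 384, 321, 357, 614 and 801, and the differences 83, 0, 2, 0, 8 and 469, in glr1, gpx1, gpx2, grx1, grx2 and yap1 (limma; 510 in gpx1 and 302 in grx1 at an unadjusted p below 0.05). Differences of the opposite sign at 6 min were ARO5 0.45 and HSP26 -0.06 in glr1, UTP6 0.18, SFG1 0.10 and YGL108C -0.19 in gpx1, and UTP6 0.28, RPA34 0.09, RTC3 -0.02 and HSP30 -0.09 in grx1. In grx2 these were UTP6 0.13, UTP15 0.11, HSP30 -0.44 and ATG17 -0.44, and in yap1 HSP30 -4.47 and YNL194C -1.09. Lists did so with 0.23 for ribosomal proteins, 0.04 for ribosome biogenesis and 0.26 for amino acid synthesis in glr1, and 0.02 for ribosome biogenesis in grx1. In grx2 ergosterol synthesis had 0.16, G2/M genes 0.20 and mating genes -0.14, and in yap1 the proteasome 0.22 and G2/M genes 0.23.

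At 12 min the responses were 1744, 1750, 2293 and 1661 in gpx1, grx1, grx2 and yap1, and the differences 37, 0, 5, 0 and 15 in glr1, gpx1, gpx2, grx1 and grx2 (166 in gpx1 and 163 in grx1 at an unadjusted p below 0.05). Opposite signs were UTP6 0.05, PCL1 0.02, RPA34 0.28, FMP48 -0.03, RTC3 -0.07 and HSP30 -0.32 in grx1, HSP30 -0.26 and ATG17 -0.77 in grx2, and HSP30 -1.38 and YNL194C -0.93 in yap1. Ribosome biogenesis had 0.16 in grx1, ergosterol synthesis 0.01 and mating genes -0.07 in grx2, and the proteasome 0.02 in yap1. At 3 min the lists of opposite sign were ribosomal proteins 0.18, ribosome biogenesis 0.16 and amino acid synthesis 0.21 in glr1, and ribosome biogenesis 0.14 in grx1. The others were ergosterol synthesis 0.10, G1/S genes 0.04 and mating genes -0.02 in grx2, and glutathione genes 0.03, the proteasome 0.23 and G2/M genes 0.00 in yap1.

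With 1 culture left out at a time the counts ran from 0 to 1, 19 to 81, 358 to 878, 1374 to 1745 and 1860 to 2098 in wild type at 0, 3, 6, 12 and 20 min. The responses ran from 2835 to 3319, 2335 to 2642, 2352 to 2596, 2452 to 2621, 3191 to 3640 and 2120 to 2424 in glr1, gpx1, gpx2, grx1, grx2 and yap1. In that order the differences ran from 119 to 979, 0 to 100, 9 to 67, 9 to 132, 859 to 1977 and 1131 to 1309, and the counts before CHP from 2 to 10, 761 to 1711, 542 to 1086, 443 to 1365, 978 to 1944 and 293 to 1027.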

Other observations

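In yap1 ROX1 and STR3 rose later than in wild type, and the genes of this paragraph were chosen after their values were seen. ROX1, a repressor of hypoxic genes, rose by 1.53 and 2.19 in wild type at 3 and 6 min and by 0.55 at 20 min, while in yap1 it had 0.01 and 0.47 at 3 and 6 min and rose by 2.12 and 2.73 at 12 and 20 min. The responses differed by -1.52, -1.71, 1.57 and 2.19 at the 4 times (adjusted p between 0.000112 and 4.43e-11). STR3, which acts in methionine synthesis, rose by 2.80 and 3.35 in wild type at 6 and 12 min and in yap1 by 2.66 and 3.01 at 12 and 20 min, a difference of -3.18 at 6 min and 2.24 at 20 min. FMP48 rose at 12 min in both, by 2.49 in wild type and 4.10 in yap1, and by 1.67 and 4.63 at 20 min. The catalase gene CTT1 rose in wild type at 12 min (1.61) and in yap1 at 20 min (3.21). FRE4 rose by 4.57 in yap1 at 12 min against 1.18 in wild type. HMX1, a heme oxygenase gene, rose by 2.27 in wild type at 20 min and by 0.77 in yap1, a difference of -1.51 (adjusted p 0.000905).

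The zinc transporter gene ZRT1 fell at 20 min in wild type (-0.85, adjusted p 0.0155), glr1 (-2.47), gpx1 (-2.61), gpx2 (-3.18) and grx2 (-2.70), and had 0.01 in yap1. It fell in grx1 too. Without the array that stands apart the grx2 fall was -2.36. The difference from wild type passed in glr1 (-1.62), gpx1 (-1.76), gpx2 (-2.33) and grx2 (-1.85, and -1.51 without that array, adjusted p 0.00845), and not in grx1 (-1.15, adjusted p 0.236) or yap1 (0.86, adjusted p 0.133). The gpx1 call of ZRT1 was lost without any one of 8 of the 12 cultures, the glr1 call without any one of 3, and those of gpx2 and grx2 stood without each of them. Over the 271 genes that rose at least 2-fold in wild type the median rise was 1.50 in wild type, between 1.83 and 2.22 in the mutants other than yap1, and 1.23 in yap1. Over the 341 that fell it was -1.37, between -1.68 and -2.21, and -0.60. These medians were not tested, and genes picked for a large change in wild type can only be compared among the mutants with that in mind. At 3 min CHP raised 63 genes in glr1, 59 in gpx1, 61 in gpx2, 56 in grx1, 75 in grx2 and 21 in yap1. HPF1, a cell wall gene, was at 6.53 in gpx2 control cultures at 0 min and 10.12 in wild type.

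Of the tests that follow, those of glr1 against gpx1 and of the rRNA signal in grx1 and grx2 were chosen after the values were seen, the others were written down before they were run, and all address patterns first seen in these data. Between gpx1 and grx1 cultures 2 genes differed before CHP, where they differed from wild type at 1641 and 1217. Unusual wild-type cultures alone are argued against, since glr1, with 4 genes apart from wild type, differed from gpx1 at 1107 genes and from grx1 at 807, and yap1 from them at 1571 and 1023. As a hypothesis, the difference may follow a batch shared by some genotypes and not each deletion. The labels name no batch, and the deletions stay open as a cause. A different share of ribosomal RNA is argued against as the whole cause for gpx1 and grx2, where 86.8% and 92.8% of the calls were left with the rRNA signal as a covariate. For grx1, whose rRNA signal was 2.24 above wild type, 57.9% were left, and it stays open there.

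In yap1 before CHP the rise of ANB1 (2.91), FET4 (1.77), COX5B (1.03), HEM13 (0.90) and AAC3 (0.82) went with a fall of ROX1 (-1.05). The 11 other hypoxic genes tested had a median of 0.03 (camera p 0.414), among them ERG11 higher by 0.41 and OLE1 at -0.98, which argues against a rise of the whole hypoxic group. Of the 10 measured genes beside the deleted ones, 0 passed in limma in their own mutant against the mean of the other genotypes (2 at an unadjusted p below 0.05), and the lowest adjusted p was 0.0518 (GIS4 in yap1, 0.14). The array of yap1, control replicate 1 at 0 min had deviations with an SD of 0.67, against a median of 0.23 over all arrays, with medians of -1.03 for proteasome and -0.68 for amino acid synthesis genes.

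With 3 cultures in each arm there are 10 splits, too few for a share under 0.05. For wild type at 0 min the real count was 0, which all 10 splits reach by design, so the comparison decides nothing (highest other 222). At 3 min 2 splits gave as many as the real 44 (highest other 390), and at 6, 12 and 20 min 1 split did, with real counts of 720, 1708 and 2186 and highest others of 447, 485 and 496. At 20 min in the mutants the real counts and highest others were 3163 and 2479 in glr1, 2777 and 425 in gpx1, 2721 and 58 in gpx2, 2753 and 209 in grx1, 3697 and 2317 in grx2, and 2515 and 120 in yap1, with 1 split as large in each. Of 100 splits of the 12 cultures before CHP, a share under 0.05 gave as many genes as the real one for gpx1 (1 split as large, real 1641, highest other 927), gpx2 (1 split, 995 and 495), grx1 (1 split, 1217 and 145), grx2 (1 split, 1645 and 1162) and yap1 (4 splits, 691 and 1044). In yap1 other splits exceeded the real count, so its case is weaker. These shares are not adjusted over the comparisons, and a batch shared by the cultures of a genotype would pass this test too. For the glr1 count chance cannot be excluded (15 splits, 4 and 568), and the highest split points to a structure of the samples there too. The splits weigh counts only: GLR1 itself passed its own limma test by far (-5.03, adjusted p 7.85e-74).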
